A study of Homo sapiens with 6 samples.

How the data were processed

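RNA sequencing libraries of cells labelled HepG2, a line derived from a human hepatocellular carcinoma, were compared. Per the labels, cells carrying a control or a CARM1 short hairpin RNA from a lentivirus received 10 µM sorafenib, a kinase inhibitor, for 24 hours. The 6 libraries formed 3 groups of 2: control, CARM1 shRNA1 and CARM1 shRNA2, as their titles give them. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

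The deposited values were estimated counts, whole numbers with no scaling between libraries. The submitters' processing notes name HISAT2 2.2.1, StringTie 2.2.1, DESeq2 and the hg38 build. How counts were derived from StringTie output, the annotation release, the use of strand and any filter are not given in the sources used here. Each of the 35177 rows was a RefSeq transcript, although the tests had been planned per gene; rows were therefore summed per gene, and the rows themselves became an alternative. A gene table of assembly GRCh38.p14 named 34545 rows, links in GENCODE 29 named 400 more, and 232 rows, with 0.243% of all counts, kept their accession. Summing gave 19442 features, of which 19210 had a symbol and 7350 joined more than 1 row. No per-sample column was left unused.

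Library totals ran from 67382155 to 74588067 counts. Low values piled up at multiples of 4. In the first control library 626 rows held 4 counts, against 352 at 3 and 398 at 5. Of genes with 1 row and 1 to 16 counts, between 32.9% and 36.1% per library lay on a multiple of 4. A sequenced fragment may thus count as about 4, and the depth in fragments is then lower than the totals. For this reason a gene at 0 in every library of a group was given a floor of 12 counts per library, standing for 3 fragments at 4 counts each. Fold bounds and floors cover counting error only, and fitted fold changes of such genes are no bounds.

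Testing used edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr by group (15540 genes), libraries were scaled by TMM (factors 0.9875 to 1.0089), and 1 quasi-likelihood model with a mean per group was fitted to all 6 libraries, leaving 3 residual degrees of freedom. Every adjusted p of a gene is from the edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes tested, and calls were made at 0.05. Standard errors were taken as the log2 fold change over the square root of F. The biological coefficient of variation was 0.164. Chi-square values per gene between replicates were 24.2 in controls, 28.6 with shRNA1 and 32.4 with shRNA2, above sampling noise if each count is taken as 1 fragment.

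Of 27 gene lists, 25 had the 3 tested members needed for camera (limma 3.58.1) with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of each contrast. Adjusted p-values with an estimated correlation are given beside them; the only calls that held with it were G2/M genes and NRF2 target genes with shRNA2. A call lost with the estimated correlation is not by itself a sign of correlated members. For G2/M genes with shRNA1 the estimate was -0.0319, below the preset, yet the unadjusted camera p rose from 1.52e-14 to 0.00331. For ribosomal protein genes with shRNA1 the estimate was 0.596. For each list called, the median, the mean and the test had the same sign. Among lists not called they could differ: fibroblast markers in the average contrast had a median of -0.23, a mean of -0.11 and an upward test. Designs, lists, alternatives and the rule for named genes were fixed before the data were examined.

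The rule named, first, CARM1 and the PRMT family members past the filter, and second, GPX4, SLC7A11, ACSL4, TFRC, HMOX1 and FTH1. The third part took genes with an average log2 CPM of at least 1, called in the same direction with both hairpins and with every knockdown library on one side of both controls: the 10 that rose and the 10 that fell by the largest average change. The next part took, per hairpin, the 5 risen and 5 fallen genes with the smallest p. Another took the 5 higher and 5 lower genes with the largest difference between hairpins at an average log2 CPM of at least 1. The last part took 4 members by p in the average contrast for each list that passed or had 3 or more members called, and 1 member of other lists. Genes without a symbol were not named.

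On simulated counts with the real means, library sizes and dispersions, 200 of 15233 tested genes were changed in a simulated shRNA1 group against control. The edgeR test recovered 47.8% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 95.5% of those changed 4-fold, with 17 false calls among 169. DESeq2 1.42.0 made 50 false calls among 224. In a simulated shRNA2 comparison, camera found 26 G2/M genes lowered 1.25-fold at an adjusted p of 5.53e-40 and called 0 of the other lists. Simulated genes were drawn independently, so this cannot show how camera treats lists with correlated members. The overlap of the hairpins was set beside 50 simulated draws of unchanged groups against shared controls.

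Alternatives fixed beforehand were DESeq2 size factors, library totals alone, no filter, a filter of 1 CPM in 4 libraries, the DESeq2 Wald test, limma-voom, robust dispersions, only the groups compared, the replicate number as a block, an added 2-fold requirement, an adjusted p under 0.01, each library left out, and for lists an estimated correlation and fry. Chosen after seeing the data were counts divided by 4, removal of ribosomal RNA rows, and transcript rows as deposited. Coordinates are those of GRCh38.p14. Overlapping and antisense genes and near-identical copies cannot be told apart here and are called uncertain. Tables were handled with pandas 2.3.3 and plots drawn with matplotlib 3.10.9.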

Results

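RNA was measured by sequencing in cells labelled HepG2 that had all received 10 µM sorafenib for 24 hours. The identity of these cells is left open below. The comparison of CARM1 knockdown with control cells asks which transcripts depend on CARM1 in the presence of this drug. CARM1 is a protein arginine methyltransferase that acts as a transcriptional coactivator. Each group had 2 libraries, with totals of 72773900 and 73197569 estimated counts in controls, 74588067 and 70282481 with shRNA1, and 71264694 and 67382155 with shRNA2. The first principal component, 24.0% of the variance, placed the controls at -51.57 and -28.48 and the 4 knockdown libraries between 16.19 and 25.16. Ribosomal RNA rows held 1.12% and 1.17% of counts in controls and 1.05% and 1.01% with shRNA2, but 0.182% and 0.0757% with shRNA1. Both shRNA1 libraries had this low share. In their comparison with control, a library difference therefore cannot be told apart from an effect of the hairpin.

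CARM1 transcripts were lower in every knockdown library than in both controls. The single CARM1 row (chromosome 19, 10871553 to 10923075) held 10052 and 10460 counts in controls, 1192 and 1372 with shRNA1, and 2943 and 2377 with shRNA2. Levels were 142 ± 3.66 CPM (SD, n = 2) in controls, 17.7 ± 2.44 with shRNA1 and 38.1 ± 4.38 with shRNA2. The log2 fold change was -3.01 (SE 0.12, adjusted p = 0.000632) with shRNA1 and -1.90 (SE 0.11, adjusted p = 0.00141) with shRNA2, and CARM1 was higher with shRNA2 than with shRNA1 by 1.11 (adjusted p = 0.0119). Tested among transcript rows as deposited, the single-hairpin changes had adjusted p = 0.0605 and 0.0578. Of the 8 PRMT family members tested, 2 fell with each hairpin and 0 rose; adjusted over the list alone, 3 fell and 1 rose with shRNA1 and 2 fell with shRNA2. The other called member was PRMT1, the main asymmetric arginine methyltransferase, at -0.38 with shRNA1 (adjusted p = 0.00512) and -0.20 with shRNA2 (adjusted p = 0.0428). PRMT2, PRMT3, PRMT5, PRMT6, PRMT7 and PRMT9 did not pass with either hairpin, with average log2 fold changes between -0.10 and 0.11. The family list, which holds the knockdown target itself, was called down with shRNA1 (camera adjusted p = 0.00364; adjusted p = 0.248 with an estimated correlation) and with shRNA2 (adjusted p = 0.0197; adjusted p = 0.237 with an estimated correlation); the call with shRNA2 was lost without the first (adjusted p = 0.107) or the second (adjusted p = 0.0512) shRNA2 library.

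**Figure D1:**
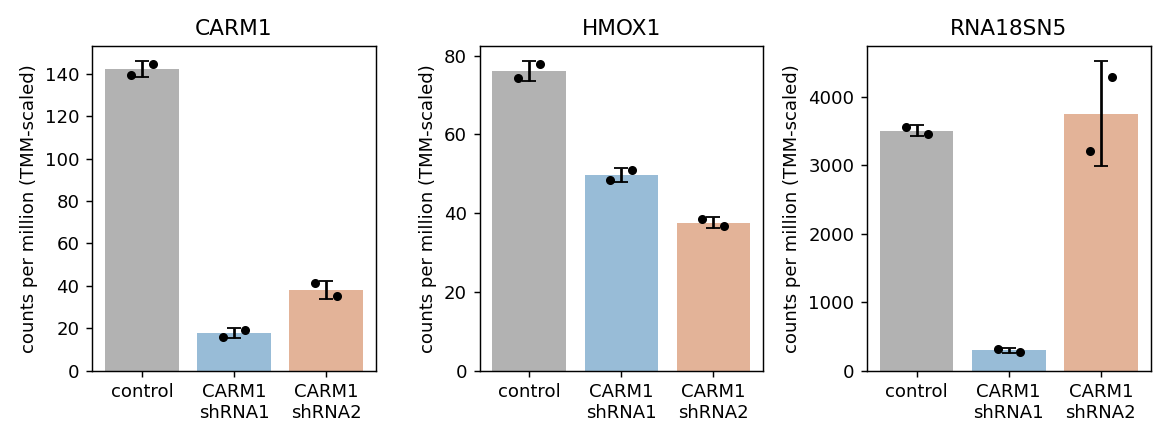
Levels of CARM1, HMOX1 and the 18S ribosomal RNA row RNA18SN5 in TMM-scaled CPM (vertical axes, from 0) in the 3 groups; bars are means, error bars SD over 2 libraries and points single libraries. CARM1 averages 142, 17.7 and 38.1 CPM in control, shRNA1 and shRNA2 libraries, and RNA18SN5 is low in the shRNA1 libraries, at 296 CPM against 3510 in controls.

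The series title names ferroptosis, an iron-dependent cell death by lipid peroxidation, so its known genes were examined next. Transcripts of GPX4, the peroxidase that reduces lipid peroxides, were at 137 ± 8.39 CPM (SD, n = 2) in controls, 133 ± 0.882 with shRNA1 and 140 ± 0.810 with shRNA2 and did not pass; the sign of the average change flips to 0.02 with library totals alone. The median of all genes in that contrast moves alike with library totals, from 0.0015 to 0.0261. SLC7A11, the cystine transporter subunit, did not pass against control with shRNA1 (0.14, adjusted p = 0.0653) or shRNA2 (-0.09, adjusted p = 0.259), while the direct difference between hairpins did (-0.23, adjusted p = 0.0427). ACSL4, which activates polyunsaturated fatty acids, had values of 0.59 and 0.77 that did not pass (adjusted p = 0.283 and 0.232), with 3336 counts in the first control library and 7214 in the other. HMOX1, the haem-degrading enzyme, fell with shRNA1 (-0.61, SE 0.05, adjusted p = 0.00439) and more with shRNA2 (-1.01, SE 0.05, adjusted p = 0.00113; difference -0.40, adjusted p = 0.0241). The ferritin subunits FTH1 (-0.21, adjusted p = 0.00806) and FTL (-0.33, adjusted p = 0.000912) and the transferrin receptor TFRC (-0.19, adjusted p = 0.028) fell with shRNA2. With shRNA1 they had values of 0.03, -0.01 and -0.12 that did not pass. Among 19 tested ferroptosis suppressors, 2 rose and 1 fell with shRNA1 (adjusted over the list alone, 3 and 1), and 1 rose and 3 fell with shRNA2 (adjusted over the list alone, 1 and 4). The heat shock protein gene HSPB1 fell (-0.33 and -0.26) and the fatty acid ligase gene ACSL3 rose (0.25 and 0.24) with both hairpins. The suppressor list was called down with shRNA2 (camera adjusted p = 0.0197; adjusted p = 0.237 with an estimated correlation) and not with shRNA1 (adjusted p = 0.876), and lost the call without the second control (adjusted p = 0.0701). Its member NFE2L2, the gene of NRF2, chosen here after its values were seen, had 3853 counts in the second shRNA2 library and 10785 to 12490 in the others. Among 27 tested drivers, 3 rose and 2 fell with shRNA1 and 0 rose and 3 fell with shRNA2 (adjusted over the list alone, 5 and 3, then 1 and 4), and the list was not called (adjusted p = 0.864 and 0.199). VDAC2, a mitochondrial channel gene, fell with both (-0.77 and -0.83), and BACH1, a haem-regulated repressor gene, rose with shRNA1 (0.30, adjusted p = 0.0152).

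Genes of mitosis and G2 phase fell with both hairpins. Of 26 G2/M genes, 17 fell and 1 rose with shRNA1 (adjusted over the list alone, 22 and 1), and 10 fell and 0 rose with shRNA2 (adjusted over the list alone, 20 and 1). The mitotic cyclin gene CCNB2 changed by -0.47 and -0.31, the spindle protein gene NUSAP1 by -0.34 and -0.41, the kinesin gene KIF20A by -0.39 and -0.28, and the centromeric histone gene CENPA by -0.54 and -0.31. The list was called down with shRNA1 (camera adjusted p = 1.9e-13; adjusted p = 0.0826 with an estimated correlation) and with shRNA2 (adjusted p = 2.67e-12; adjusted p = 0.0472 with an estimated correlation). Outputs of ERK signalling, which sorafenib targets upstream, rose: 6 of 17 rose and 0 fell with shRNA1, and 5 rose and 1 fell with shRNA2 (adjusted over the list alone, 7 and 2, then 6 and 2). CCND1 rose by 0.25 and 0.26, the phosphatase gene DUSP4 by 0.51 and 0.38, PHLDA1 by 0.38 and 0.47, and the AP-1 subunit gene FOSL1 by 0.49 and 0.47. That list was called up at adjusted p = 0.0158 and 0.0102 (camera), and lost the call with an estimated correlation, at adjusted p = 0.459 and 0.263 with an estimated correlation. It was also lost without the second shRNA1 library for shRNA1 (adjusted p = 0.117) and without the first shRNA2 library for shRNA2 (adjusted p = 0.0601).

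In all, 168 genes rose and 104 fell with both hairpins, and 6 were called in opposite directions. Independent lists of these sizes would share 14.4 risen and 8.67 fallen genes. Unchanged groups simulated against shared controls shared on average 0.480 and 0.220, at most 2 and 3. Across genes, which are not independent replicates, the Pearson correlation of the fold changes was 0.557, and between 0.440 and 0.563 in the simulated draws; the covariance was 0.335 against a simulated 0.117. At an average log2 CPM of at least 1 the correlation was 0.438 against 0.492 and the covariance 0.0566 against 0.0322. The controls were not split between the hairpins, so part of the excess may come from the shared controls. Every knockdown library lay on one side of both controls for 31.3% of genes. Chance gives 13.3% only if all 6 libraries are exchangeable. Libraries of a group may share a culture, and any difference between groups can then raise the share. The 2 values are thus no measure of a shared CARM1 effect. With library totals alone 223 rose and 72 fell. The count of 272 was 62 and 70 without the first and second control. It was 64 and 55 without the first and second shRNA1 library and 175 and 126 without the first and second shRNA2 library. A total of 1 transcript row was called with both hairpins when rows were tested as deposited.

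The genes with the largest changes shared by both hairpins, taken by the rule for named genes, came from several functions. Among the fallen, MIR34AHG, the host transcript of a p53-induced microRNA, had 1154 and 1287 counts in controls, 22 and 15 with shRNA1, and 14 and 4 with shRNA2. LSS, the lanosterol synthase gene of cholesterol synthesis, fell from 41.0 ± 2.74 CPM (SD, n = 2) to 15.1 ± 1.07 and 15.3 ± 0.506, and 2 of the 25 cholesterol synthesis genes fell with each hairpin; most of the fall of LSS lay in 1 of its 3 transcript rows. COMMD9 (-1.08 and -1.01), the arrestin-domain gene ARRDC4 (-1.12 and -1.19), ACTL8 (-0.84 and -1.30) and EFHD1 (-0.91 and -0.95) also fell. So did the histone genes H2AC6 (-1.20 and -1.06) and H2BC5 (-0.85 and -0.77), whose close copies make them uncertain. Among the risen, MAPK4 (1.66 and 1.72), the calcium channel subunit gene CACNG8 (1.33 and 1.97) and the EGF-family ligand gene EPGN (1.44 and 1.75) rose, as did the cytokine gene IL1A (3.85 CPM in controls, 9.19 and 8.79). The elongation factor gene EEF1A2 (1.33 and 1.00), DHRS2 (1.03 and 1.23), the adaptor gene PAG1 (3.71 CPM in controls, 8.86 and 6.66), the NAD synthesis gene QPRT (1.14 and 0.93) and PSG4 (1.23 and 1.24), one of a family of close copies and so uncertain, rose as well. Each named value passed at an adjusted p of 0.0362 or less (edgeR quasi-likelihood, Benjamini-Hochberg).

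**Figure D2:**
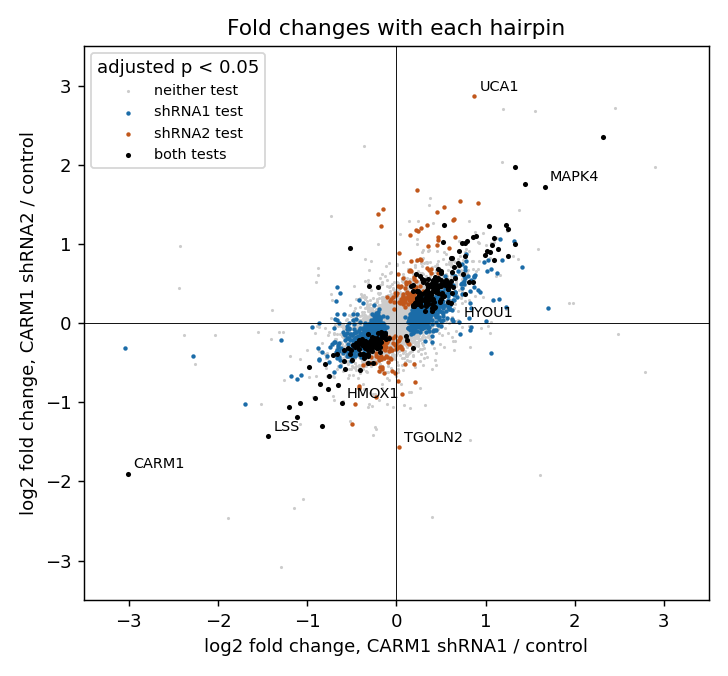
Log2 fold changes against control with CARM1 shRNA1 (horizontal axis) and shRNA2 (vertical axis); each point is a gene with an average log2 CPM of at least 1, coloured by the tests it passed, and genes beyond the axis range are not drawn. CARM1 lies at -3.01 and -1.90, and TGOLN2 at 0.03 and -1.57.

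With shRNA1, chaperone genes of the endoplasmic reticulum rose and ribosomal protein genes fell, beside the low ribosomal RNA share of these libraries (0.182% and 0.0757%, against 1.12% and 1.17% in controls). The library difference seen in that share cannot be told apart from an effect of shRNA1 on these lists or on the genes called. Of 20 unfolded protein response genes 15 rose and 0 fell (adjusted over the list alone, 18). HYOU1 rose from 463 ± 5.68 to 751 ± 5.23 CPM (SD, n = 2; 0.70, adjusted p = 0.000632), the chaperone gene HSPA5 by 0.40, CALR by 0.40 and HERPUD1 by 0.46; HSPA5 (0.15) and CALR (0.19) also passed with shRNA2. The list was called up (camera adjusted p = 2.92e-13; adjusted p = 0.199 with an estimated correlation). Of 32 ribosomal protein genes 29 fell and 0 rose (adjusted over the list alone, 31), by a median of -0.19, with RPS4X at -0.26, RPLP1 at -0.27, RPL19 at -0.22 and RPL4 at -0.14 (camera adjusted p = 8.64e-15; adjusted p = 0.518 with an estimated correlation); processed copies make this family uncertain. Of 4 metallothionein genes 3 fell (also 3 adjusted over the list alone), MT1E by -0.53 (camera adjusted p = 0.00217; adjusted p = 0.248 with an estimated correlation). Of 27 oxidative phosphorylation genes 1 rose and 2 fell (adjusted over the list alone, 1 and 2), SDHD at -0.22 (camera adjusted p = 0.0176; adjusted p = 0.82 with an estimated correlation). That call was lost without the first control (adjusted p = 0.113) or the second shRNA1 library (adjusted p = 0.123). The genes with the smallest p included CCN5 (1.00), TCEA1 (0.71) and AHNAK2 (0.77) among the risen and IFI16 (-0.71) and RNA18SN5 (-3.57) among the fallen. Of these, CCN5 (0.87), AHNAK2 (0.85) and IFI16 (-0.41) also passed in the same direction with shRNA2, whereas TCEA1 (-0.14) and RNA18SN5 (0.10) did not pass with it. LIMS3-LOC440895, a readthrough locus in a duplicated region and so uncertain, had 0 counts in both shRNA1 libraries and was at least 37.8-fold lower than in controls. In total 808 genes rose and 705 fell, 54 and 29 of them by 2-fold or more, and with library totals alone the split was 953 and 533. The count of 1513 was 190 and 187 without the first and second control and 238 and 173 without the first and second shRNA1 library, and 2 transcript rows were called when rows were tested as deposited.

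With shRNA2, targets of the oxidative stress regulator NRF2 fell, while 3 fibroblast markers and 3 acute phase or NF-kB targets rose. Of 28 NRF2 target genes 10 fell and 0 rose (adjusted over the list alone, 23), with a median of -0.23 (camera adjusted p = 4.56e-15; adjusted p = 0.0472 with an estimated correlation). HMOX1 (-1.01), FTL (-0.33), the quinone reductase gene NQO1 (-0.31, adjusted p = 0.00806) and PIR (-0.31) were among them. With shRNA1, 3 of these 28 rose and 5 fell (adjusted over the list alone, 6 and 6) and the list was not called (adjusted p = 0.83). Of 8 tested fibroblast markers 3 rose and 0 fell (adjusted over the list alone, 3 and 1): the proteoglycan genes LUM (1.24, 22.5 to 53.1 CPM, adjusted p = 0.000548) and DCN (1.46), and COL3A1 (0.39); COL1A1 was at -0.30 and did not pass (camera adjusted p = 0.00844; adjusted p = 0.237 with an estimated correlation). COL6A1 (1.02) and the proteoglycan gene CSPG4 (1.01) also rose. With shRNA1, LUM (0.53), COL6A1 (0.52) and CSPG4 (0.77) passed in the same direction, as did NQO1 (-0.24), PIR (-0.18) and BIRC3 (0.44). Of 12 acute phase and NF-kB targets 3 rose (adjusted over the list alone, 5): BIRC3 (0.47), CXCL8 (1.08) and IL6 (0.79), while TNFAIP3 was at 0.23 and did not pass (camera adjusted p = 0.00844; adjusted p = 0.237 with an estimated correlation). Of 32 ribosomal protein genes 2 fell (adjusted over the list alone, 15; camera adjusted p = 7.07e-05; adjusted p = 0.548 with an estimated correlation). Of 20 unfolded protein response genes 2 rose (adjusted over the list alone, 4; camera adjusted p = 0.0498; adjusted p = 0.466 with an estimated correlation). Of 24 p53 targets 0 passed in edgeR, also adjusted over the list alone, 0 in limma-voom and 3 in DESeq2, with 5 at an unadjusted p under 0.05, and the list was called down (camera adjusted p = 0.0293; adjusted p = 0.237 with an estimated correlation). TGOLN2, a trans-Golgi protein gene, fell from 194 ± 2.27 to 65.4 ± 4.33 CPM (SD, n = 2; -1.57, adjusted p = 0.00037), and the cyclophilin gene PPIB by -0.73. Fibroblast markers lost the call without the first control (adjusted p = 0.0888) or the second shRNA1 (0.0655) or shRNA2 library (0.109). So did p53 targets without the second control (0.0733) or the first shRNA2 library (0.107). Unfolded protein response genes lost it without the first (0.123) or second control (0.111) or the first (0.0588) or second shRNA2 library (0.109). ZBTB9 had 665 and 728 counts in controls and 0 in both shRNA2 libraries, at least 55.1-fold lower. In total 277 genes rose and 191 fell, 45 and 12 of them by 2-fold or more, and with library totals alone the split was 349 and 140. The count of 468 was 107 and 129 without the first and second control. It was 193 and 189 without the first and second shRNA1 library and 306 and 214 without the first and second shRNA2 library, while 39 transcript rows were called when rows were tested as deposited.

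Averaged over both hairpins, 642 genes rose and 562 fell against control (830 and 422 with library totals alone), and 6 lists were called, 0 of them with an estimated correlation. The lists were G2/M genes, ribosomal protein genes, NRF2 targets and the PRMT family, lower, and unfolded protein response and ERK output genes, higher. The PRMT family holds the knockdown target itself. The count of 1204 was 139 and 121 without the first and second control and 434 and 361 without the first and second shRNA1 library, and 20 transcript rows were called when rows were tested as deposited.

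**Figure D3:**
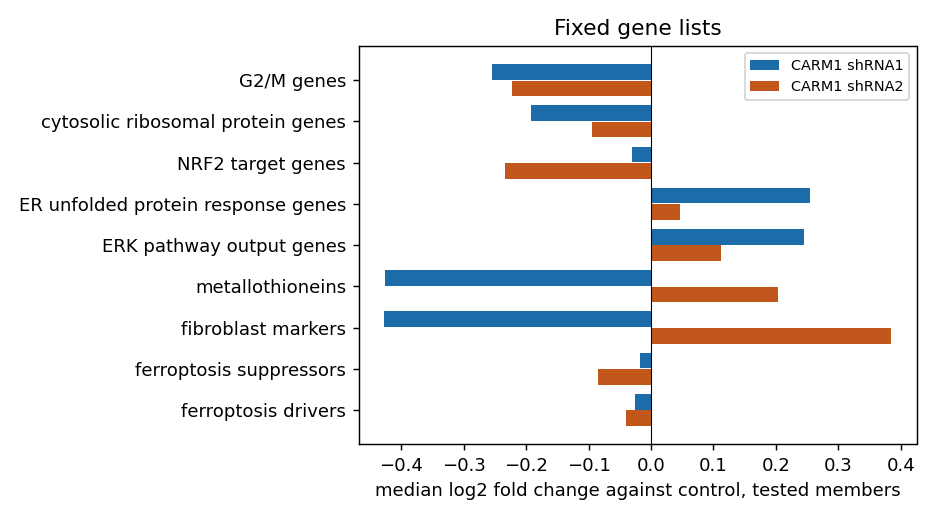
Median log2 fold change against control over the tested members of 9 of the gene lists (horizontal axis) with CARM1 shRNA1 and shRNA2 (bar colours). G2/M genes lie at -0.26 and -0.22, and NRF2 target genes at -0.03 and -0.23.

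The hairpins differed directly in 153 genes that were higher and 191 that were lower with shRNA2 than with shRNA1. NRF2 targets were lower with shRNA2 (13 of 28 members; adjusted over the list alone, 20; camera adjusted p = 1.22e-13; adjusted p = 0.0765 with an estimated correlation), as were unfolded protein response genes (7 of 20; adjusted over the list alone, 17; camera adjusted p = 1.07e-12; adjusted p = 0.104 with an estimated correlation). Metallothioneins (3 of 4; adjusted over the list alone, 4), fibroblast markers (4 of 8; adjusted over the list alone, 4) and ribosomal protein genes (3 of 32; adjusted over the list alone, 18) were higher. Their camera adjusted p-values were 2.61e-07, 1.97e-06 and 2.72e-07, and adjusted p = 0.104, 0.104 and 0.394 with an estimated correlation. The long noncoding RNA UCA1 was higher with shRNA2 (1.99), and the matrix gene SPARC (-1.52), the mucin gene MUC13 (-1.44) and the isoprenoid gene IDI1 (-0.96) were lower. RNA18SN5 (3.67), RNA28SN5 (2.72) and RNA5-8SN5 (1.86) were higher. For these rows a library difference of the shRNA1 group cannot be told apart from an effect of the hairpins. The same holds for other genes and lists in this comparison that moved with shRNA1 against control. MUC13 had 297 and 296 counts with shRNA1, 131 and 150 in controls and 116 and 94 with shRNA2. UCA1 instead moved mainly with shRNA2. It had 801 and 927 counts there, 126 and 120 in controls and 191 and 262 with shRNA1. The count of 344 was 111 and 117 without the first and second control. It was 45 and 60 without the first and second shRNA1 library and 221 and 96 without the first and second shRNA2 library, and 14 transcript rows were called when rows were tested as deposited.

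The remaining lists were not called with either hairpin. Of 30 integrated stress response genes 2 rose and 2 fell with shRNA1 and 2 fell with shRNA2, with TRIB3 at -0.16 and -0.17 and GDF15 at 0.47 and -0.02 (adjusted over the list alone, 5 and 4, then 0 and 2; camera adjusted p = 0.876 and 0.0876). Cholesterol synthesis, fatty acid, G1/S, interferon, hypoxia, lysosome, nuclear receptor and mesenchymal lists had camera adjusted p-values between 0.463 and 0.876 with shRNA1 and between 0.0571 and 0.735 with shRNA2. Members rising and falling with shRNA1 were 0 and 2 of 25 for cholesterol, 3 and 1 of 17 for fatty acid, 2 and 3 of 25 for G1/S, 3 and 0 of 25 for interferon, 4 and 3 of 27 for hypoxia, 6 and 0 of 21 for lysosome, 1 and 0 of 11 for nuclear receptor and 3 and 4 of 20 for mesenchymal genes. Adjusted over the list alone they were 0 and 3, 3 and 1, 2 and 4, 3 and 0, 5 and 4, 6 and 1, 1 and 0, and 3 and 5. With shRNA2, in the same order, they were 0 and 2, 1 and 1, 1 and 0, 1 and 1, 1 and 2, 2 and 0, 0 and 0, and 4 and 1. Adjusted over the list alone they were 0 and 2, 1 and 4, 1 and 0, 1 and 2, 3 and 3, 4 and 2, 0 and 0, and 5 and 3. Lists called with the other hairpin were not called for p53 targets with shRNA1 (4 rose and 4 fell; adjusted p = 0.935), acute phase targets with shRNA1 (2 rose; adjusted p = 0.598) or fibroblast markers with shRNA1 (1 rose and 2 fell; adjusted p = 0.876). Nor were oxidative phosphorylation with shRNA2 (adjusted p = 0.671) or metallothioneins with shRNA2 (adjusted p = 0.107) called. Hepatocyte genes, which HepG2 cells are known to express, were near the floor in all groups: 15 of 32 had a row, 3 of them averaged 1 CPM or more, and ALB had 0 counts in 5 libraries and 4 in the other. CEBPA averaged 10.9 CPM, VTN 2.02 and HNF4A 0.199, while the mesenchymal gene VIM was at 897 ± 2.41 CPM (SD, n = 2) in controls. Endothelial, leukocyte and hepatocyte lists had 3, 3 and 7 members tested and were not called (camera adjusted p from 0.83 to 0.91 with shRNA1 and from 0.67 to 0.82 with shRNA2), with VWF at 0 and 5 counts and CSF1R at 1.97 CPM in controls. VTN was higher with shRNA1 by 1.06 (adjusted p = 0.0463). Squamous markers had 2 members tested and no list test. With shRNA1 KRT16 rose (0.77, adjusted p = 0.0285) and SFN, chosen after its values were seen, fell (-0.29, adjusted p = 0.0345). With shRNA2 they were at 0.71 and -0.22 and did not pass (adjusted p = 0.0602 and 0.112). No row was matched to any of the 13 mitochondrially encoded genes, so that list had no test.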

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

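The tests weighed here were chosen after the result was seen; the tests of the difference between hairpins were planned. The hairpins target the same gene, but their libraries also differed in ribosomal RNA share (0.182% and 0.0757% with shRNA1, 1.05% and 1.01% with shRNA2). This library difference is weighed below for NRF2 targets only. By a direct test 344 genes differed between shRNA2 and shRNA1, and 6 genes were called in opposite directions against control. Named from these 6 after their values were seen, with the log2 difference of shRNA2 minus shRNA1, were CYB561 (-0.50), RSPO3 (1.48), TGFBI (0.65), TGM2 (0.77) and TXNRD1 (-0.27); the other had no symbol.

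By the same direct test, the list medians of the log2 difference were -0.24 for NRF2 targets, -0.22 for unfolded protein response genes, -0.08 for p53 targets and -0.01 for ferroptosis suppressors. They were 0.74 for fibroblast markers, 0.54 for metallothioneins, 0.15 for acute phase and NF-kB targets, 0.13 for mesenchymal and matrix genes, 0.11 for ribosomal protein genes, 0.06 for oxidative phosphorylation genes and 0.03 for the PRMT family, which holds CARM1 itself. None of these 11 lists was called with an estimated correlation, where the smallest camera adjusted p was 0.0765; with the preset correlation all 11 were. The estimate exceeded the preset 0.01 only for unfolded protein response (0.0953), oxidative phosphorylation (0.129), mesenchymal (0.2035) and ribosomal protein genes (0.599). For the other lists the lost call cannot be laid to correlated members. Without 1 library, the calls of PRMT family, ferroptosis suppressor, acute phase, p53 and oxidative phosphorylation lists were lost in 1 or more cases, at adjusted p from 0.0617 to 0.173.

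Named genes lower with shRNA2 than with shRNA1 were TGOLN2 (-1.60), SPARC (-1.52), MUC13 (-1.44), IDI1 (-0.96), TCEA1 (-0.85), PPIB (-0.75), HYOU1 (-0.68), ABCC2 (-0.52), GDF15 (-0.49), ACTL8 (-0.47), HMOX1 (-0.40), FTL (-0.33), HSPA5, FTH1 and CDKN1A (each -0.24), SLC7A11 (-0.23) and CALR (-0.21). Higher were RNA18SN5 (3.67), RNA28SN5 (2.72), UCA1 (1.99), RNA5-8SN5 (1.86), CARM1 (1.11), DCN (0.92), LUM (0.71), MT1E (0.53), COL6A1 (0.50), ITGA5 (0.41), IFI16 (0.30), COL3A1 (0.28), RPLP1 (0.19) and RPS4X (0.14). ZBTB9, at 0 in both shRNA2 libraries, was at least 70.4-fold lower with shRNA2, and LIMS3-LOC440895, at 0 in both shRNA1 libraries, at least 35.0-fold higher.

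NRF2 targets fell with shRNA2, which left more CARM1 than shRNA1. Depth of knockdown as the whole cause would make the larger fall that of shRNA1, against the observed median difference of -0.24. A scaling factor per library moves every gene alike and is argued against by the list's median less that of all tested genes, -0.24 (order-statistic interval of at least 95%, -0.33 to -0.15, with genes taken as independent, which they are not). The library difference seen as low ribosomal RNA in the shRNA1 libraries is argued against by the fall of shRNA2 against control, -0.23, since those groups had similar ribosomal RNA shares. An effect of a hairpin on other transcripts, or a difference between the stable cell populations, may account for it and was not tested.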

How the results depend on the processing

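Counts divided by 4, removal of ribosomal RNA rows and transcript rows as deposited were tests chosen after seeing the data. The genes called, in the order shRNA1, shRNA2, average, shRNA2 against shRNA1, and both hairpins, were 1513, 468, 1204, 344 and 272. In that order they were 2777, 1646, 2532, 1505 and 940 with the DESeq2 Wald test, which made more false calls on simulated data, 83, 57, 59, 23 and 21 with an added 2-fold requirement, and 207, 90, 192, 36 and 41 at an adjusted p under 0.01. On transcript rows as deposited they were 2, 39, 20, 14 and 1. Robust dispersions gave 1081, 1914, 882 and 608 from shRNA2 on. With only the groups compared, shRNA2, the direct difference and both hairpins had 255, 123 and 148, and without a filter shRNA2 and the direct difference had 308 and 174; the cause of these shifts was not tested. DESeq2 size factors, library totals alone, limma-voom, a stricter filter, counts divided by 4 and removal of ribosomal RNA rows moved each count by at most 1.5 times.

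With the replicate number as a block, the counts were 745, 186, 512, 65 and 105 in the order above. The check of pairing does not support the replicate block: deviations from group means correlated between groups by -0.0415, -0.0474 and 0.0169, near 0.

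Leaving out 1 library gave 173 to 1564 genes with shRNA1, 107 to 306 with shRNA2, 121 to 1052 for the average, 45 to 221 for the direct difference and 55 to 175 with both hairpins. A group left with 1 library was assumed to vary like the others, and fewer libraries lower the power. Of 127 tests of named genes, 60 were lost without the first control and 60 without the second, 36 and 39 without the first and second shRNA1 library, and 13 and 17 without the first and second shRNA2 library. No gene called changed sign in any of these alternatives on gene sums.

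CARM1 averaged between -2.39 and -2.53 in every alternative and passed in each; on transcript rows the single-hairpin values were -3.01 (adjusted p = 0.0605) and -1.90 (adjusted p = 0.0578). Lists called numbered 6 for the average, 7 with shRNA1, 10 with shRNA2 and 11 for the direct difference. With an estimated correlation they were 0, 0, 2 and 0. The fry test gave 12 for the average and, for changes in either direction, 22 in each contrast, which compares no list with other genes. Without 1 library the direct difference had 7 to 13 lists called. Average values that did not pass turned sign for 4 genes, and the cause was not tested. GPX4 was at 0.0207 with library totals and 2e-04 with the stricter filter, and ranged from -0.0658 without the second control to 0.0594 without the first. SLC7A11 ranged from -0.0079 without the first control to 0.0619 without the second, and PRMT9 from -0.0662 without the first shRNA2 library to 6e-04 without the first control. VWF ranged from -0.5772 without the first shRNA2 library to 6.6721 without the second control, a fitted value against 0 counts and so no bound. Dividing counts by 4 gave 1676, 605, 1420, 408 and 360 genes, more in each case than without, and calls at low counts were not tested separately.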

Other observations

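The tests on hepatocyte genes were chosen after their levels were seen; those on transcript rows were written before their results. The lysosomal protease genes CTSD (0.39 and 0.30) and CTSL (0.36 and 0.28) rose with both hairpins. The glycolysis genes ENO1 (-0.12 and -0.20) and GAPDH (-0.12 and -0.13) fell with both, while the interferon-induced gene IFIT2 (0.41 and 0.31) and the glucose transporter gene SLC2A1 (0.36 and 0.35) rose.

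Hepatocyte genes were near the floor in all 6 libraries labelled HepG2, and a loss of the most abundant transcripts in the authors' processing was tested in 2 ways, the second chosen after the first had given its result. Regulators of hepatocyte genes, which are not abundant, had a median of 1.62 CPM, above the bound of 1 CPM set for that explanation, though they lay far apart; 77 genes averaged 1000 CPM or more, between the bounds set and so undecided, and the explanation stays open. Cells of another identity than the label gives may also account for it: 3 of the 15 listed hepatocyte genes with a row, 20%, reached 1 CPM, exactly on the bound set, and no reference library of HepG2 was used here. Of 10 fibroblast markers, 6 averaged 1 CPM or more, with COL3A1 the highest at 221 CPM, and these levels also lacked a reference. Hepatocyte members without a row were not counted. Counting them as unexpressed would put the hepatocyte share under the bound, on the side of this explanation, which stays open. Loss of the hepatocyte programme under sorafenib cannot be told apart from these, since 0 libraries were without the drug.

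Far fewer calls were made on transcript rows than on gene sums, 2 against 1513 with shRNA1. Among rows averaging 100 counts or more, 36.2% of rows of genes with several rows differed by 2-fold or more between replicates in some group, 15.2 times the 2.38% of genes with 1 row, and sums of the former differed in 2.30%. Reads of a gene divided differently between its rows in each library are therefore a candidate explanation for genes with several rows. Division of its own reads cannot account for CARM1, whose single row held the same counts but lost both single-hairpin calls. The biological coefficient of variation was 0.755 over rows and 0.164 over gene sums. Its part in calls lost by genes with 1 row was not tested. A harsher adjustment over more rows is argued against by unadjusted p-values, since the share of rows under 0.05 was at most 0.48 of the share of gene sums over the 4 contrasts.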
